A study of Mus musculus with 12 samples.

How the data were processed

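Gene expression was measured in 12 libraries of 3T3-L1 cells in 4 groups of 3. Per the labels' protocols, 30 ng of RNA per sample was barcoded at reverse transcription and pooled, following MARS-seq. Cells 2 days past confluence were induced for 2 days with 0.5 mM IBMX, 1 µM dexamethasone, 1 µg/mL insulin and 2 µM rosiglitazone in medium with 10% serum and then kept for 2 days in insulin. Per the submitters' processing notes, cutadapt, HTSeq and DESeq2 were used with the build mm10; versions and the annotation are not given in the sources used here.

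The authors deposited 1 table of 11035 genes. Its counts are whole UMI counts per gene as deposited by the authors, not normalized. Its normalized signal was made by the authors by dividing those counts by 1 size factor per library, which was checked from the values (largest relative departure from 1 constant per library, 5.1e-15). Its log2 fold changes and its p-values are the authors' deposited comparison results and enter no test here. Only counts of genes under the threshold are reported from them. Every gene of the table reached at least 6 counts in some library. The table holds 88 ribosomal protein genes and 0 mitochondrially encoded genes.

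Groups and replicate numbers come from the sample titles. Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr on the groups, and a robust quasi-likelihood fit of all 12 libraries with 4 group means. Of 11035 genes 9519 were tested and 1516 were not. P-values were two-sided and adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The common biological coefficient of variation was 0.126 and the median prior degrees of freedom 19.2. Log2 CPM used a prior count of 2. Gene lists, 33 in all with 550 genes of which 390 were tested, were fixed with the design and the alternatives before the data were examined. The 28 lists with at least 5 tested members were tested by camera (limma 3.58.1, preset correlation 0.01), with an estimated correlation as alternative and fry beside it. Over the 4 comparisons, camera called 19, 15, 17 and 20 lists, and 14, 12, 14 and 14 of these also with an estimated correlation. Python 3.11.15 and matplotlib 3.10.9 drew the figures.

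The genes named were chosen by a rule: a fixed set (Pparg, Cebpa, Adipoq, Fabp4, Plin1, Lpl, Ccl2, Cxcl1, Col1a1, Cd274, and Trp53 once), the 5 largest called rises and 5 largest called falls per comparison with replicates that do not overlap and a mean of at least 20 CPM, and up to 4 called members per list by size of change. Il6 belongs to the fixed set and was not analysed here. Some members behind small list counts are not reported here, but stay in the counts of gene results examined. Which of the genes under this rule the text names was settled after their values and a first run of the alternatives had been seen. Genes outside the rule are marked where they stand as chosen after their values were seen. A gene at 0 counts in a group is compared with a floor of 3 counts over the group, and one with 1 to 3 counts is given as a ratio with a 95% counting interval; floors and intervals cover counting error only.

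Gene coordinates and identifiers were taken from GENCODE vM21 on mm10; 145 of 145 genes examined by name matched. For each gene, the last 500 bases of its transcripts were searched in stretches of 31 bases, every 10 bases, for copies in other genes. Genes with over 10% shared are given as uncertain. The search took in all genes of another name and did not measure whether whole genes are near-identical.

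The tests were checked on simulated counts with 200 genes changed. For regular_diff against preadipocyte, edgeR recovered 71.1% of 2-fold and 97.9% of 4-fold changes over 9049 genes. For WT_CM against regular_diff it recovered 71.7% and 92.6% over 8942 genes, for KO_CM against regular_diff 51.1% and 89.4% over 8910 genes, and for KO_CM against WT_CM 58.2% and 91.8% over 9039 genes. In the same order, 12, 10, 6 and 9 unchanged genes were called. A planted list was called in each, and 0 of 20 random lists. The simulated genes varied independently of one another, so this does not check camera on lists of correlated genes. In the data, the list of fatty acid uptake and insulin response had an estimated correlation of 0.22 under differentiation.

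The alternatives were DESeq2 1.42.0, other scalings and filters, fits of only the 6 libraries compared, no robust fit, no ribosomal protein genes, a replicate block, and each replicate left out in turn. Added after seeing the data were leaving out preadipocyte replicate 5 and KO_CM replicate 1 together, and thinning all libraries to the smallest total. Also added then were removing a trend over the GC content of whole transcripts, and choosing the differentiation sets in a fit of only the preadipocyte and regular_diff libraries.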

Results

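Gene expression was measured in mouse 3T3-L1 cells, a fibroblast line that turns into fat cells under hormone treatment, with MARS-seq, which counts the 3′ ends of transcripts by unique molecular identifiers. The 12 libraries fall into 4 groups of 3. The preadipocyte group was undifferentiated. The regular_diff group was differentiated with an adipogenic cocktail of IBMX, dexamethasone, insulin and rosiglitazone. The WT_CM and KO_CM groups were differentiated in the same media mixed with equal parts of medium conditioned by WEA breast cancer cells, with p53 intact in WT_CM and knocked out in KO_CM. No group received the same mix with unconditioned medium. In comparisons with regular_diff, any dilution of the inducers or depletion of the medium therefore cannot be told apart from factors of the cancer cells. Replicates are numbered 4 to 6 in preadipocyte and regular_diff and 1 to 3 in WT_CM and KO_CM libraries. If the numbers mark separate sets or days, these too cannot be told apart from conditioned medium in comparisons with regular_diff. Total counts per library were 1458452 to 1836626 in preadipocyte, 1387854 to 1801316 in regular_diff and 1758814 to 2025317 in WT_CM libraries. The KO_CM libraries were shallower, with 748693, 1132099 and 669007 counts in replicates 1, 2 and 3. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The p53 knockout was made in the cancer cells, so Trp53 in the 3T3-L1 cells checks no label. Trp53 stood at 85.6 ± 33.8 CPM in preadipocyte, 39.5 ± 10.9 in regular_diff, 31.2 ± 4.00 in WT_CM and 46.6 ± 13.9 in KO_CM libraries (mean ± SD, n = 3 each). It was lower in regular_diff than in preadipocyte by -1.10 ± 0.31 at an adjusted p of 0.0118, and at 0.0709 with only the 6 libraries compared (edgeR's quasi-likelihood test, Benjamini-Hochberg; range over the alternatives 2.66e-10 to 0.0709), and was called in no other comparison. Values below are CPM, counts scaled to library size, as mean ± SD over 3 libraries, or log2 fold changes ± SE. The SE comes from the fit, so its spread is estimated over all libraries fitted, also those outside the comparison.

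On mm10, in the annotation GENCODE vM21, the protein-coding gene Pparg lies on chromosome 6 from 115360951 to 115490399, Cebpa on chromosome 7 from 35119293 to 35121928, and Adipoq on chromosome 16 from 23146536 to 23158028. Plin1 lies on chromosome 7 from 79720218 to 79732903 and Ccl2 on chromosome 11 from 82035571 to 82037453. Serpina3n lies on chromosome 12 from 104406729 to 104414329 and Angptl7 on chromosome 4 from 148495183 to 148500460.

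What the standard protocol changed was asked by comparing regular_diff with preadipocyte libraries. The labels give days past confluence, in induction and in insulin for the differentiated groups but not for preadipocytes. Any difference in confluence or time in culture therefore cannot be told apart from the inducers here, and is part of what is called differentiation below. Genes of fat storage and oxidation rose, and genes of the interferon response, matrix, contraction and chemokines fell. Pparg, the nuclear receptor that drives fat cell formation, rose from 49.2 ± 6.29 to 879 ± 36.8 CPM, a log2 fold change of 4.16 ± 0.13. Cebpa, a transcription factor that acts with it, rose from 12.6 ± 1.21 to 397 ± 10.4 CPM, by 4.97 ± 0.14. Of 9519 genes tested, 4874 were called at an adjusted p under 0.05 (edgeR's quasi-likelihood test, Benjamini-Hochberg), 2364 higher and 2510 lower, and 2480 of them changed at least 2-fold. Scaling by library size alone gave 5126 genes, 1905 higher and 3221 lower, with the median of all genes shifted by -0.16. The authors' deposited table held 4370 genes under the same threshold.

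All 14 tested adipocyte transcription factors rose (14 adjusted over the list alone), among them Klf15 by 7.68 ± 0.27. Mlxipl, a glucose-sensing factor of the same list, was at 0 counts in preadipocytes and at least 13.4-fold higher against a floor of 3 counts over the group. Of 13 lipid droplet and lipolysis genes, 12 rose (13 adjusted over the list alone), with Plin1, a coat protein of fat droplets, up by 8.36 ± 0.23 and Cidec, which enlarges droplets, up by 8.78 ± 0.54. Of 19 fatty acid and triglyceride synthesis genes, 18 rose and 1 fell (18 and 1 adjusted over the list alone): Thrsp, a regulator of fat synthesis, rose by 9.93 ± 0.25, Pck1 was at least 92.3-fold higher, and Elovl6, a fatty acid elongase, changed by -1.88 ± 0.45. All 13 genes of fatty acid uptake and insulin response rose (13 adjusted over the list alone), including the insulin-responsive glucose transporter Slc2a4 by 8.37 ± 0.30 and Lpl by 4.27 ± 0.15. The fatty acid receptor Cd36 had a count ratio of 153 (95% counting interval 42.1 to 1270). Of 9 adipokines, 8 rose and 1 fell (8 and 1 adjusted over the list alone): Adipoq rose by 8.16 ± 0.85, Cfd by 8.25 ± 0.78 and Retn by 7.67 ± 0.55, and the peptide hormone Adm changed by -1.18 ± 0.19. All 25 genes of mitochondrial oxidation rose (25 adjusted over the list alone), Acadm by 3.28 ± 0.13 and Idh3a by 2.93 ± 0.11. Of 12 acute phase genes 8 rose and 2 fell (8 and 2 adjusted over the list alone): Steap4 rose by 5.14 ± 0.34 and Orm1 by 8.20 ± 0.29, while Ptx3 changed by -1.69 ± 0.12 and Serpina3g by -3.91 ± 0.58. Other large rises were the nicotinic acid receptor Hcar2, at least 118-fold, Aatk, at least 121-fold, and carbonic anhydrase Car3, with a count ratio of 908 (95% counting interval 163 to 35900). Elovl6, Adm, Ptx3 and Serpina3g were chosen after their values were seen. Other genes share 38.3% of the stretches searched in Orm1, 46.8% in Serpina3g and 11.2% in Elovl6, so these 3 are uncertain. The genes given here with a log2 value passed at an adjusted p of at most 0.000932 (edgeR's quasi-likelihood test, Benjamini-Hochberg). The 7 lists were called by camera at an adjusted p of at most 0.000482, and with an estimated correlation at an adjusted p of at most 0.0415.

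Adipoq and Fabp4, a fatty acid carrier of adipocytes, were also counted in preadipocytes, unevenly: Adipoq had 129 counts in replicate 5 against 13 and 11 in replicates 4 and 6, and Fabp4 had 564 against 86 and 94. Fabp4 rose by 6.56 ± 0.81. Cfd had 97 counts in replicate 5 against 12 and 8, Retn 35 against 5 and 3, and Cidec 37 against 5 and 6. Without preadipocyte replicate 5 and KO_CM replicate 1, which stood apart from their groups, the rises were 10.32 ± 0.16 for Adipoq, 8.11 ± 0.13 for Fabp4, 10.28 ± 0.16 for Cfd, 9.53 ± 0.19 for Retn and 10.36 ± 0.17 for Cidec, an alternative chosen after the data were seen.

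Of 22 interferon-stimulated genes 21 fell (22 adjusted over the list alone), Ifit1 by -5.82 ± 0.45, Oasl2 by -5.73 ± 0.33 and Mx2 by -4.73 ± 0.44. Of 17 fibrillar matrix genes 14 fell and 1 rose (14 and 1 adjusted over the list alone): Tnc changed by -3.62 ± 0.31, fibronectin (Fn1) by -2.75 ± 0.11, Col1a1 by -1.77 ± 0.15 and the collagen Col5a3 by 0.65 ± 0.10. Of 16 matrix proteases and inhibitors 12 fell and 2 rose (12 and 2 adjusted over the list alone): the gelatinase Mmp9 changed by -5.53 ± 0.41 and Mmp19 by 0.60 ± 0.18. Col5a3 and Mmp19 were chosen after their values were seen. Of 10 contractile genes 9 fell (10 adjusted over the list alone), smooth muscle actin (Acta2) by -3.80 ± 0.39 and Myl9 by -3.34 ± 0.29. Of 9 chemokines 8 fell (8 adjusted over the list alone): the monocyte attractant Ccl2 went from 134 ± 25.3 to 17.0 ± 5.86 CPM, a change of -2.96 ± 0.19, and Cxcl5 changed by -3.15 ± 0.25. Of 14 preadipocyte and stromal progenitor genes 9 fell (9 adjusted over the list alone), Gata2 by -3.07 ± 0.38. Genes outside these lists with the largest falls were Ptprv at -5.55 ± 0.39 and the BMP antagonist Grem1 at -5.24 ± 0.90. The genes named here passed at an adjusted p of at most 0.00966 (edgeR's quasi-likelihood test, Benjamini-Hochberg). The 6 lists were called by camera at an adjusted p of at most 6.72e-05, and with an estimated correlation at an adjusted p of at most 0.00764.

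What medium of p53-intact cancer cells changed was asked by comparing WT_CM with regular_diff libraries. The mixing of the media is part of this comparison. Acute phase, complement and chemokine genes rose. Genes of fat synthesis and mitochondrial oxidation fell, with list medians of -0.48 and -0.41, and Pparg and Plin1 showed no called change. Serpina3n, a secreted protease inhibitor of the acute phase, rose from 48.4 ± 3.69 to 1533 ± 110.3 CPM, by 4.99 ± 0.38. Ccl2 rose from 17.0 ± 5.86 to 89.4 ± 5.54 CPM, by 2.37 ± 0.20. Pparg stood at 879 ± 36.8 against 766 ± 21.6 CPM, a log2 fold change of -0.20 ± 0.11 that was not called, and Plin1 at 0.01 ± 0.11. Col1a1, at 0.22 ± 0.15, was not called. In all 943 genes were called (edgeR's quasi-likelihood test, Benjamini-Hochberg, adjusted p under 0.05), 545 higher and 398 lower, 298 of them by at least 2-fold. The authors' deposited table held 666. Without regular_diff replicate 4 the count was 595, without regular_diff replicate 6 it was 621, with only the 6 libraries compared it was 1480, without preadipocyte replicate 5 and KO_CM replicate 1 it was 1445, and with counts thinned to the smallest total it was 506.

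Of 12 acute phase genes 9 rose and 2 fell (9 and 2 adjusted over the list alone): Serpina3n rose most, and the serum amyloid gene Saa3 rose by 3.65 ± 0.53, while Orm1 changed by -0.79 ± 0.14 and Orm2 by -1.49 ± 0.35. Haptoglobin (Hp), of the same list, rose by 3.84 ± 0.80 at an adjusted p of 0.018 (edgeR's quasi-likelihood test, Benjamini-Hochberg; range over the alternatives 2.99e-37 to 0.0879). The adjusted p of Hp was above 0.05 without regular_diff replicate 4 (0.0879), 5 (0.0818) or 6 (0.0787) and without WT_CM replicate 3 (0.0534), while its log2 fold change stayed between 3.79 and 3.93. Without regular_diff replicate 4 the adjusted p of Orm2 was 0.0632 (range 0.000965 to 0.0632). Orm1 and Orm2 were chosen after their values were seen. Other genes share 38.3% of the stretches searched in Orm1, 42.6% in Orm2 and 11.3% in Saa3, so their counts are uncertain. Of 9 complement genes 5 rose (8 adjusted over the list alone), among them Masp1, a protease of the lectin pathway, by 1.79 ± 0.18. Of 9 chemokines 6 rose (6 adjusted over the list alone): Ccl9 by 2.83 ± 0.41, Cxcl5 by 2.05 ± 0.27 and Cxcl1 by 1.11 ± 0.24. Of 12 NF-kB response genes 5 rose (5 adjusted over the list alone), Bcl3 by 2.69 ± 0.22 and Nfkbiz by 0.99 ± 0.22. Of 16 matrix proteases and inhibitors 6 rose (9 adjusted over the list alone), Timp1 by 2.19 ± 0.18 and Serpine2 by 1.15 ± 0.15. Of 20 cell cycle genes 10 rose (13 adjusted over the list alone), Birc5 by 1.34 ± 0.24 and Top2a by 1.23 ± 0.25. With counts thinned to the smallest total, the adjusted p of Cxcl5 was 0.0757 (range over the alternatives 1.24e-07 to 0.0757), that of Nfkbiz 0.0798 (0.000603 to 0.0798) and that of Birc5 0.108 (2.67e-05 to 0.108), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Their log2 fold changes were then 1.24, 0.97 and 0.95, so that of Cxcl5 shrank most. Other large rises were the tenascin Tnn at 4.56 ± 0.42, the protease inhibitor Slpi at 3.67 ± 0.22 and Lrg1 at 3.56 ± 0.34. Apart from Hp, the rises and falls given here passed at an adjusted p of at most 0.00454 (edgeR's quasi-likelihood test, Benjamini-Hochberg). The 6 lists were called by camera at an adjusted p of at most 5.53e-06, and with an estimated correlation at an adjusted p of at most 0.0182.

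Of 19 fatty acid and triglyceride synthesis genes 11 fell under WT_CM (12 adjusted over the list alone), Thrsp by -2.40 ± 0.13 and Pck1 by -1.80 ± 0.21. Of 25 mitochondrial oxidation genes 16 fell (22 adjusted over the list alone), Fh1, the fumarase of the citric acid cycle, by -0.64 ± 0.11. Camera called these 2 lists at an adjusted p of at most 2.89e-10, and with an estimated correlation at an adjusted p of 0.0145 for each. Of 14 adipocyte transcription factors 1 fell (2 adjusted over the list alone), Klf15 by -1.39 ± 0.14, and of 13 lipid droplet genes 1 rose (3 adjusted over the list alone), Plin2 by 0.59 ± 0.11. The transcription factor list was called at an adjusted p of 0.042 by camera, but at an adjusted p of 0.131 with an estimated correlation. That call was also lost without regular_diff replicate 4 (adjusted p 0.0579) or 6 (0.0658) and without WT_CM replicate 2 (0.101) or 3 (0.0779), over a range of 0.00985 to 0.131. Of 13 genes of uptake and insulin response 4 fell (6 adjusted over the list alone). Camera called that list lower at an adjusted p of 0.00514, but at an adjusted p of 0.151 with an estimated correlation. Cebpa was at -0.30 ± 0.10, Adipoq at -0.44 ± 0.60 and Fabp4 at 0.19 ± 0.63, none of them called. Cebpa was called lower with only the 6 libraries compared (adjusted p 0.00454), with preadipocyte replicate 5 and KO_CM replicate 1 left out (0.00677) and with a GC trend removed (0.0365), over a range of 0.00454 to 0.17 (edgeR's quasi-likelihood test, Benjamini-Hochberg). With both doubted libraries (preadipocyte replicate 5 and KO_CM replicate 1) left out, Adipoq was at -0.43 ± 0.08 and called. Its adjusted p was 2.80e-05 (edgeR's quasi-likelihood test, Benjamini-Hochberg), with a range of 2.31e-06 to 0.87 over the alternatives. In that fit Cidec, of the lipid droplet list, was also called lower, at -0.77 ± 0.08. So were the adipokines Cfd, at -0.41 ± 0.08, and Retn, at -0.78 ± 0.09. The adjusted p-values of these genes were at most 8.3e-05 (same test), while Fabp4, at 0.19 ± 0.08, was not called there. Cidec, Cfd and Retn were chosen here after their values were seen. Lpl fell by 0.57 ± 0.12 on the log2 scale, and was not called with only the 6 libraries compared, at an adjusted p of 0.12 (edgeR's quasi-likelihood test, Benjamini-Hochberg; range 0.000181 to 0.12). Other large falls were the water channel Aqp2 at -4.57 ± 0.46, Smoc1 at -2.38 ± 0.31, Adh1 at -2.17 ± 0.22 and the matrix protein Fmod at -2.12 ± 0.24. The called falls, Lpl included, and the rise of Plin2 passed at an adjusted p of at most 0.00283 (edgeR's quasi-likelihood test, Benjamini-Hochberg).

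What medium of p53-knockout cancer cells changed was asked by comparing KO_CM with regular_diff libraries, which again differ in the mixing of the media. Adipocyte genes fell across the lists of fat storage, synthesis and oxidation, and matrix, protease, progenitor, contractile and chemokine genes rose. Pparg fell from 879 ± 36.8 to 258 ± 45.5 CPM, a log2 change of -1.77 ± 0.12, and Cebpa from 397 ± 10.4 to 133 ± 17.1 CPM, by -1.58 ± 0.11. Ccl2 rose from 17.0 ± 5.86 to 264 ± 33.6 CPM, by 3.93 ± 0.19. In all 3290 genes were called (edgeR's quasi-likelihood test, Benjamini-Hochberg, adjusted p under 0.05), 1639 higher and 1651 lower, 1557 of them by at least 2-fold. Scaling by library size alone gave 1876 higher and 1447 lower, so the balance depends on the scaling. The authors' deposited table held 2802. The KO_CM libraries held fewer counts than all others, which limits what low genes can show.

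Of 14 adipocyte transcription factors 10 fell (11 adjusted over the list alone), Klf15 by -3.29 ± 0.19. Of 13 lipid droplet genes 11 fell (12 adjusted over the list alone), Cidec by -2.91 ± 0.38, G0s2, an inhibitor of fat breakdown, by -2.50 ± 0.28, and Plin1 by -1.46 ± 0.13. Of 19 synthesis genes 17 fell (18 adjusted over the list alone), Pck1 by -3.42 ± 0.31 and Thrsp by -2.55 ± 0.14. Of 13 genes of uptake and insulin response 11 fell (11 adjusted over the list alone), Slc2a4 by -2.52 ± 0.18 and Lpl by -1.34 ± 0.13. All 25 mitochondrial oxidation genes fell (25 adjusted over the list alone), Acadm by -1.65 ± 0.12 and Idh3a by -1.58 ± 0.10. Other large falls were Apoa4, an apolipoprotein, at -6.36 ± 0.34, Cyp2ab1 at -5.06 ± 0.42 and Igfals at -4.59 ± 0.43. The falls named so far passed at an adjusted p of at most 0.000365 (edgeR's quasi-likelihood test, Benjamini-Hochberg). The 5 lists were called by camera at an adjusted p of at most 1.62e-07, and with an estimated correlation at an adjusted p of at most 0.00639. Adipoq changed by -2.16 ± 0.62 at an adjusted p of 0.0269 (edgeR's quasi-likelihood test, Benjamini-Hochberg; range over the alternatives 5.04e-25 to 0.0823). Its adjusted p was above 0.05 without KO_CM replicate 1 (0.0679), 2 (0.0612) or 3 (0.0823) and without regular_diff replicate 4 (0.0627), 5 (0.0625) or 6 (0.0648). Fabp4, at -1.47 ± 0.65, was not called in the fit of all 12 libraries. With only the 6 libraries compared it was called, at -1.46 and an adjusted p of 1.15e-05 (edgeR's quasi-likelihood test, Benjamini-Hochberg). With both doubted libraries left out, Fabp4 was at -1.31 ± 0.09, at an adjusted p of 2.29e-17 (edgeR's quasi-likelihood test, Benjamini-Hochberg; range 2.29e-17 to 0.254).

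Of 16 matrix proteases and inhibitors 14 rose under KO_CM (14 adjusted over the list alone): Mmp9 by 4.17 ± 0.53, the plasminogen activator Plat by 3.24 ± 0.17 and Serpine2 by 3.23 ± 0.14. Of 17 fibrillar matrix genes 12 rose and 1 fell (12 and 1 adjusted over the list alone): Thbs1 by 3.49 ± 0.16, Tnc by 3.11 ± 0.35, the collagen cross-linker Lox by 2.82 ± 0.11 and Col1a1 by 1.17 ± 0.15, with Col5a3 at -0.55 ± 0.11. Of 14 progenitor genes 10 rose (11 adjusted over the list alone), the stromal receptor Pdgfra by 2.45 ± 0.18 and Dlk1, an inhibitor of fat cell formation, by 1.35 ± 0.30. Of 10 contractile genes 8 rose (9 adjusted over the list alone), Cnn2 by 2.51 ± 0.11 and Myl9 by 2.38 ± 0.36. Of 9 chemokines 7 rose (7 adjusted over the list alone), Cxcl5 by 3.14 ± 0.27 and Cxcl1 by 1.35 ± 0.26. Among the largest rises were Grem1 at 7.06 ± 0.77, Tnn at 6.42 ± 0.36 and Saa3 at 6.11 ± 0.43. Angptl7, a secreted angiopoietin-like protein, had a count ratio of 133 (95% counting interval 36.2 to 1110) and Gpr176 one of 63.7 (16.9 to 537). Dlk1 and Col5a3 were chosen after their values were seen. The rises and falls given with a log2 value passed at an adjusted p of at most 0.000828 (edgeR's quasi-likelihood test, Benjamini-Hochberg). The 5 lists were called by camera at an adjusted p of at most 5.28e-08, and with an estimated correlation at an adjusted p of at most 0.00175.

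Some lists moved both ways under KO_CM. Of 9 complement genes 5 rose and 2 fell (6 and 2 adjusted over the list alone): C1s1 rose by 2.45 ± 0.12 and Masp1 by 2.60 ± 0.18, C3 changed by -0.48 ± 0.11 and Cfb by -1.12 ± 0.42. Of 12 NF-kB response genes 9 rose and 1 fell (9 and 1 adjusted over the list alone), Bcl3 by 2.39 ± 0.24 and Nfkbia, the inhibitor of NF-kB, by -0.47 ± 0.17. Of 22 interferon-stimulated genes 11 rose and 2 fell (11 and 2 adjusted over the list alone), Oasl2 by 3.12 ± 0.50 and Ifi27l2a by -1.12 ± 0.20. C3, Cfb, Nfkbia and Ifi27l2a were chosen after their values were seen. The genes named here passed at an adjusted p of at most 0.0418 (edgeR's quasi-likelihood test, Benjamini-Hochberg). Camera called the 3 lists at an adjusted p of at most 0.00928, and the complement and NF-kB lists also with an estimated correlation, at an adjusted p of at most 0.00577, but the interferon list only at an adjusted p of 0.167. The fall of Cfb was not called without regular_diff replicate 4 (adjusted p 0.127) or 5 (0.0721) or KO_CM replicate 1 (0.168) or 3 (0.0777), over a range of 0.0371 to 0.168 (edgeR's quasi-likelihood test, Benjamini-Hochberg). That of Nfkbia was lost without regular_diff replicate 4 (0.132), 5 (0.0844) or 6 (0.145) or KO_CM replicate 1 (0.0907) or 2 (0.303, at -0.27), over a range of 0.0126 to 0.303. Other genes share 34.2% of the stretches searched in C1s1 and 87.3% in Cfb, so these are uncertain.

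**Figure D1:**
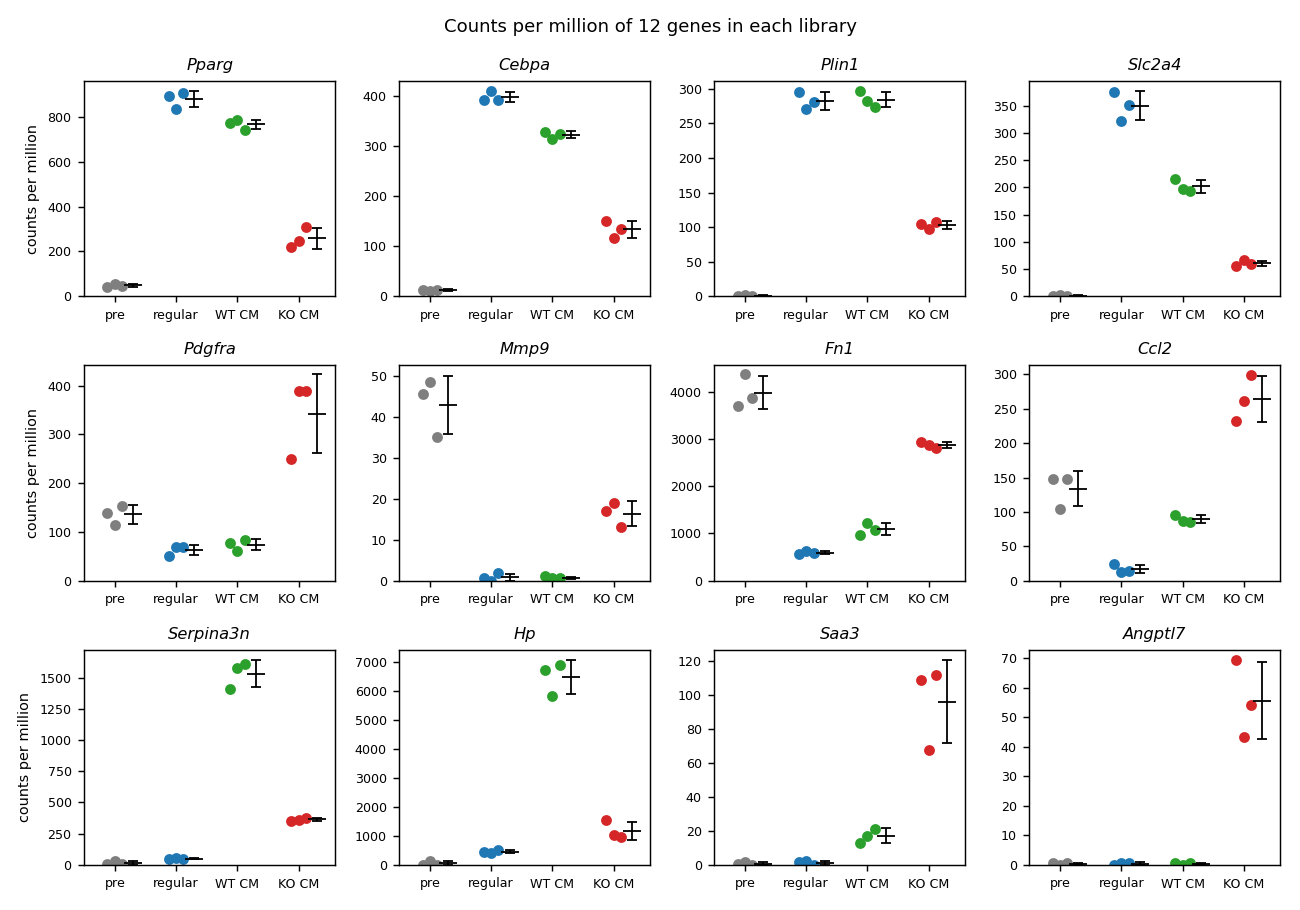
CPM (counts scaled to library size adjusted by TMM) of 12 genes in the 4 groups, with dots for libraries and bars for the mean ± SD over 3 libraries. Pparg averages 879 CPM in regular_diff, 766 in WT_CM and 258 in KO_CM, and Ccl2 averages 17.0, 89.4 and 264.

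How medium of p53-knockout cancer cells differed in effect from medium of p53-intact ones was asked by comparing KO_CM with WT_CM libraries directly. The labels name no separate clones of the cancer cells or batches of their medium. Differences of clone, cell number or batch therefore cannot be told apart from the loss of p53. Under KO_CM, adipocyte genes were lower and matrix, protease, progenitor and contractile genes higher than under WT_CM, while acute phase genes were mostly lower than under WT_CM. Pparg fell from 766 ± 21.6 to 258 ± 45.5 CPM, by -1.57 ± 0.12, Cebpa by -1.28 ± 0.11 and Plin1 by -1.47 ± 0.13. Ccl2 rose from 89.4 ± 5.54 to 264 ± 33.6 CPM, by 1.56 ± 0.15. In all 2625 genes were called (edgeR's quasi-likelihood test, Benjamini-Hochberg, adjusted p under 0.05), 1298 higher and 1327 lower, 1054 of them by at least 2-fold. Scaling by library size alone gave 1482 higher and 1161 lower, which turns the balance. The authors' deposited table held 2076.

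Of 14 adipocyte transcription factors 7 were lower in KO_CM (8 adjusted over the list alone), Klf15 by -1.90 ± 0.21. Of 13 lipid droplet genes 12 were lower (12 adjusted over the list alone), Cidec by -2.14 ± 0.37, G0s2 by -2.13 ± 0.28 and Plin4 by -1.75 ± 0.14. Of 19 synthesis genes 16 were lower (16 adjusted over the list alone), Pck1 by -1.63 ± 0.36. Of 13 genes of uptake and insulin response 9 were lower (10 adjusted over the list alone), Slc2a4 by -1.73 ± 0.19 and Lpl by -0.78 ± 0.13. Of 25 mitochondrial oxidation genes 24 were lower (25 adjusted over the list alone), Acadm by -1.21 ± 0.12 and Cpt2, of fatty acid import, by -1.24 ± 0.17. Of 12 acute phase genes 8 were lower and 1 higher (9 and 3 adjusted over the list alone): Steap4 by -2.30 ± 0.17 and Serpina3n by -2.08 ± 0.33, with Saa3 higher by 2.46 ± 0.27. Hp, of the same list, was lower by -2.46 ± 0.75 at an adjusted p of 0.0419 (edgeR's quasi-likelihood test, Benjamini-Hochberg; range over the alternatives 2.20e-27 to 0.122). Its adjusted p was above 0.05 without WT_CM replicate 1 (0.0915), 2 (0.0785) or 3 (0.0935) and without KO_CM replicate 1 (0.0698), 2 (0.118) or 3 (0.122), and was 0.109 with a replicate block, while its log2 fold change stayed between -2.69 and -2.30 over the alternatives. Adipoq at -1.73 ± 0.62 and Fabp4 at -1.66 ± 0.65 were not called in the fit of all 12 libraries. There the uneven preadipocyte libraries enter the estimate of the spread. With only the 6 libraries compared, Adipoq at -1.72 and Fabp4 at -1.66 were called. Their adjusted p-values were then 3.3e-09 and 4e-06 (edgeR's quasi-likelihood test, Benjamini-Hochberg). With both doubted libraries left out they were at -1.66 ± 0.09 and -1.5 ± 0.09, at adjusted p-values of 7.27e-21 and 4.04e-19 (edgeR's quasi-likelihood test, Benjamini-Hochberg; ranges up to 0.171 and 0.223). Other large falls were Apoa4 at -4.51 ± 0.42, Cyp2ab1 at -4.41 ± 0.45, Lrg1 at -3.64 ± 0.38, the neutrophil protease Prtn3 at -3.49 ± 0.36 and the fatty acid receptor Ffar4 at -3.25 ± 0.51. Apart from Hp, the genes called here passed at an adjusted p of at most 0.00272 (edgeR's quasi-likelihood test, Benjamini-Hochberg). The 6 lists were called by camera at an adjusted p of at most 0.000251, and with an estimated correlation at an adjusted p of at most 0.0407. Other genes share 11.3% of the stretches searched in the transcript end of Saa3. Against regular_diff, 5 of the 12 acute phase genes rose in KO_CM and 2 fell (6 and 2 adjusted over the list alone). Camera did not call the list there, at an adjusted p of 0.0702, and of 0.21 with an estimated correlation.

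Of 17 fibrillar matrix genes 13 were higher in KO_CM than in WT_CM and 1 lower (14 and 1 adjusted over the list alone): Lox by 2.67 ± 0.10, Thbs2 by 1.92 ± 0.15 and Col1a1 by 0.94 ± 0.15, with Col5a3 at -0.91 ± 0.10. Of 16 matrix proteases and inhibitors 12 were higher and 1 lower (12 and 1 adjusted over the list alone): Mmp9 by 4.34 ± 0.52 and Plat by 2.75 ± 0.16. Of 14 progenitor genes 9 were higher (9 higher and 1 lower adjusted over the list alone), Dlk1 by 2.57 ± 0.34 and Pdgfra by 2.21 ± 0.18. Of 10 contractile genes 6 were higher (6 adjusted over the list alone), Myl9 by 2.16 ± 0.34 and Cnn2 by 1.83 ± 0.11. Of 9 chemokines 4 were higher (4 adjusted over the list alone), Ccl5 by 1.91 ± 0.45 and Cxcl12 by 1.21 ± 0.10, and Cxcl1 at 0.24 ± 0.23 was not called. Angptl7 had a count ratio of 151 (95% counting interval 41.0 to 1260), and Osr2, a transcription factor, was higher by 3.46 ± 0.29 and Mamdc2 by 3.00 ± 0.41. Decorin (Dcn) was higher by 2.99 ± 0.75 at an adjusted p of 0.0181 (edgeR's quasi-likelihood test, Benjamini-Hochberg; range over the alternatives 0.000323 to 0.0662). Its adjusted p was above 0.05 without WT_CM replicate 1 (0.0502), 2 (0.058) or 3 (0.0662) and without KO_CM replicate 2 (0.0631). Col5a3 was chosen after its value was seen. Apart from Dcn and Cxcl1, the genes given with a log2 value passed at an adjusted p of at most 0.00167 (edgeR's quasi-likelihood test, Benjamini-Hochberg). The 5 lists were called by camera at an adjusted p of at most 0.00324, and with an estimated correlation at an adjusted p of at most 0.0305.

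Complement genes moved both ways between the media. Of 9 tested, 4 were higher and 3 lower in KO_CM (4 and 3 adjusted over the list alone): C1s1 by 1.95 ± 0.12, C1ra by 1.69 ± 0.15, C1rb by 1.5 ± 0.14 and Masp1 by 0.80 ± 0.15, against C3 at -0.74 ± 0.11, C4b at -1.65 ± 0.17 and Cfb at -1.89 ± 0.38, at an adjusted p of at most 0.000366 (edgeR's quasi-likelihood test, Benjamini-Hochberg). Other genes share 34.2% of the stretches searched in C1s1, 25.5% in C1ra, 51.1% in C1rb, 37.1% in C4b and 87.3% in Cfb. C3, C1rb and Masp1 were chosen after their values were seen. Camera called the list higher at an adjusted p of 0.043, but at an adjusted p of 0.175 with an estimated correlation, and at 0.0915 without WT_CM replicate 1 and 0.0502 without WT_CM replicate 2 (range 0.00395 to 0.175).

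**Figure D2:**
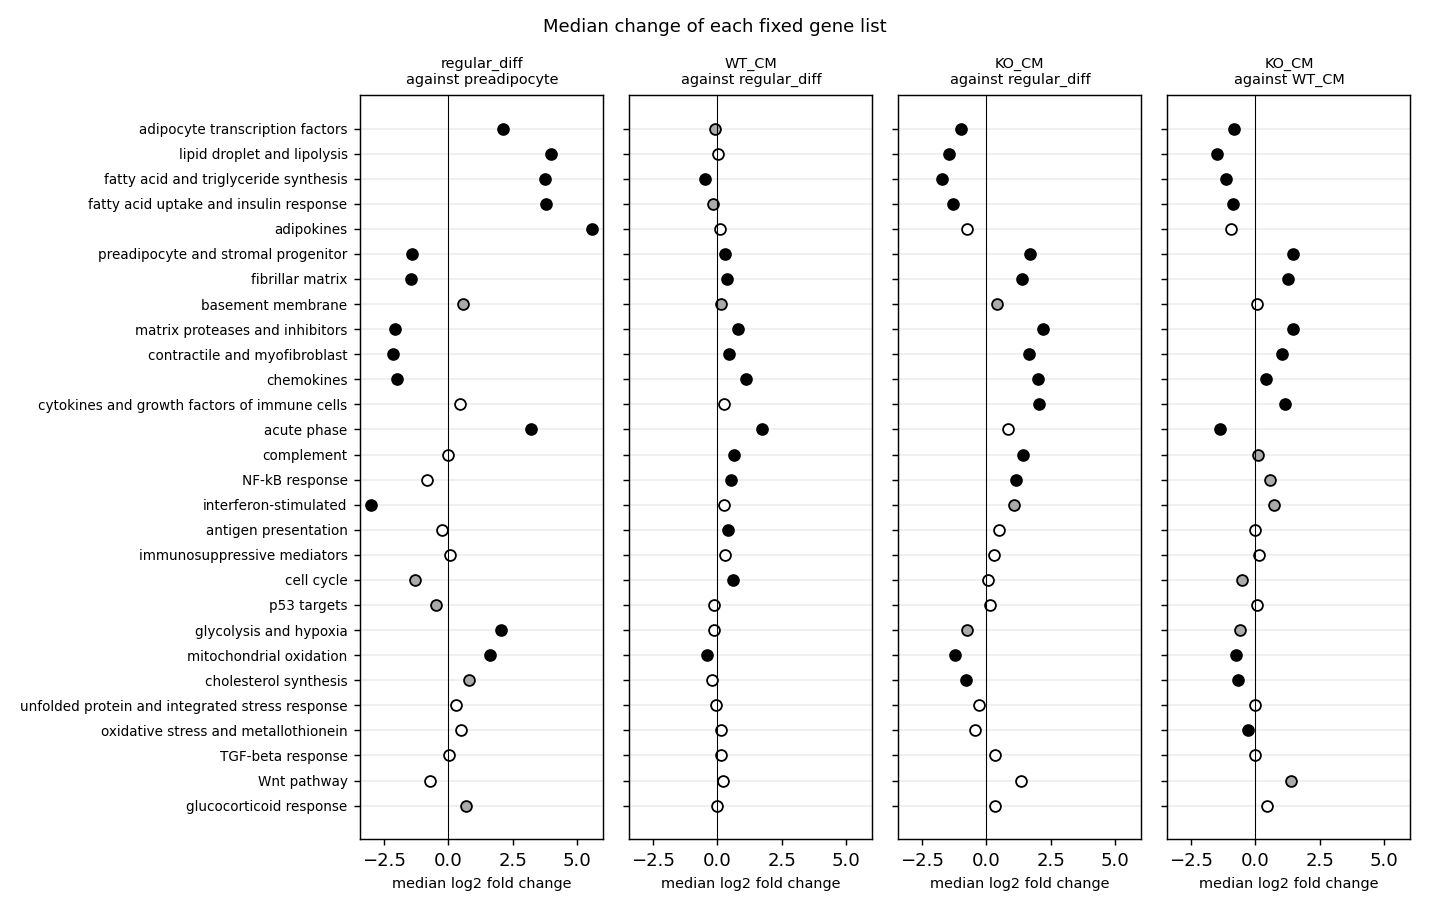
Median log2 fold change of the 28 tested gene lists in the 4 comparisons, with black points for lists called by camera with the preset and the estimated correlation, grey for the preset alone and white for neither. The mitochondrial oxidation list has a median of 1.61 under differentiation, -0.41 in WT_CM against regular_diff, -1.21 in KO_CM against regular_diff and -0.74 in KO_CM against WT_CM.

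Where each medium left the genes of differentiation was asked with the genes that differed at least 2-fold between preadipocyte and regular_diff libraries. These were taken from the comparison of regular_diff with preadipocyte in the fit of all 12 libraries, where WT_CM and KO_CM libraries enter the estimate of the spread. Of the 1277 genes raised by differentiation, 824 were lower in KO_CM than in WT_CM and 11 higher, with a median of -0.81. Of the 1203 lowered genes, 665 were higher and 10 lower, with a median of 0.89. Camera gave p-values of 8.16e-63 and 3.47e-49, and 1.3e-06 and 1.5e-09 with an estimated correlation. A fit of only the preadipocyte and regular_diff libraries, chosen after the data were seen, gave sets of 1204 and 1120 genes, 1187 and 1116 of them in common with these. A score over these genes, set to 0 at the preadipocyte mean and 100 at the regular_diff mean, was 85.7 ± 0.605 in WT_CM and 40.5 ± 1.65 in KO_CM libraries (SD, n = 3), with a spread of 1.82 in preadipocyte and 1.41 in regular_diff libraries. The difference of -45.1 had a two-sided exact permutation p of 0.1, the smallest that 3 against 3 libraries can give. The lowered set also holds genes such as Ccl2, which rose under WT_CM while Pparg and Plin1 were not called there. A response of such genes to the media lowers the score too, so it does not measure the extent of differentiation alone. Over the 9519 genes tested, the log2 fold changes of differentiation and of KO_CM against WT_CM had a Pearson correlation of -0.72 and a Spearman correlation of -0.713 across genes, which are not independent replicates.

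**Figure D3:**
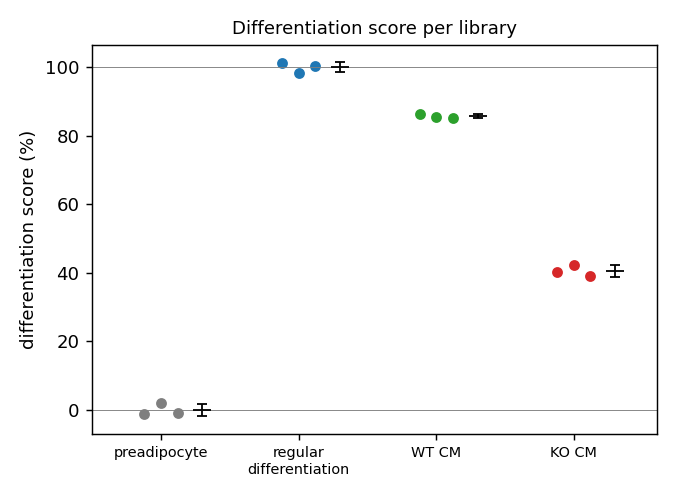
Differentiation score of each library in percent, 0 being the preadipocyte mean and 100 the regular_diff mean, with points for libraries. The KO_CM libraries lie between 39.1 and 42.3 and the WT_CM libraries between 85.2 and 86.3.

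**Figure D4:**
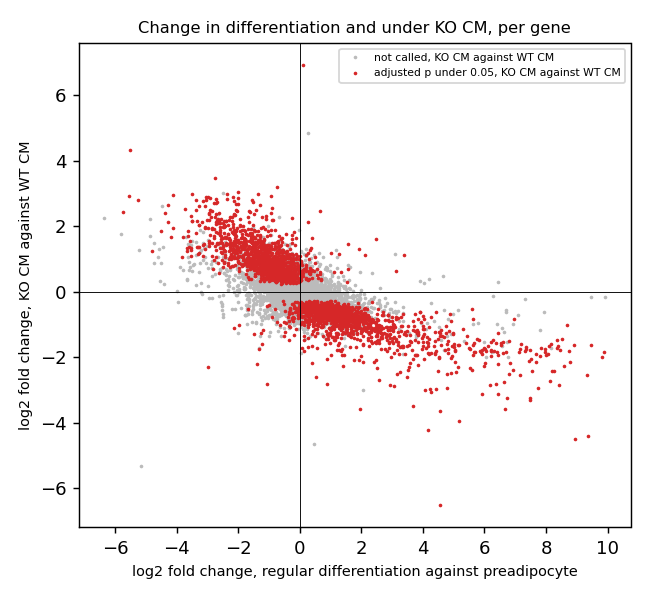
Log2 fold change of each tested gene in regular_diff against preadipocyte (horizontal) and in KO_CM against WT_CM (vertical), with red points for an adjusted p under 0.05 in KO_CM against WT_CM (edgeR's quasi-likelihood test, Benjamini-Hochberg). The points fall along a downward slope, with a Pearson correlation of -0.72 across 9519 genes.

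Whether both media moved genes in common was asked from the calls against regular_diff. Of the 545 genes higher in WT_CM and the 1639 higher in KO_CM, 391 were in both lists, against 93.8 for independent lists. Of the 398 and 1651 lower genes 339 were in both, against 69.0. The total was 730 against 163, and 37 genes were called in opposite directions. Tnn, Saa3, Ccl2, Thbs1 and Bcl3 were higher and Klf15, Thrsp and Pck1 lower in both. The fold changes had a correlation of 0.603 across genes against a mean of 0.432 in 20 simulated draws of unchanged groups against the same controls, and a covariance of 0.283 against 0.0499, a difference of 0.233. The 3 control libraries cannot be split into 2 sets of 2 or more, so part of the excess may come from the shared controls. Both CM groups also shared the mixing of the media and the replicate numbers 1 to 3, which regular_diff did not have.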

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

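Thinning and leaving out both doubted libraries (preadipocyte replicate 5 and KO_CM replicate 1), which enter the values of Dlk1 here, were tests chosen after the data were seen, the other tests were not, and the genes Card14, Cyb561, Sbsn, Atp10d, Wfdc21 and Sncg were chosen after their values were seen. Both media were compared with the same regular_diff libraries, and 37 genes were called in opposite directions under them, against 730 in the same direction. The difference between KO_CM and WT_CM was called for all 37 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. That difference rests on the same libraries, so it adds no separate support. There were 29 genes higher under WT_CM and lower under KO_CM, and 8 genes lower under WT_CM and higher under KO_CM. In KO_CM against WT_CM, the log2 fold change was -3.49 for the neutrophil protease Prtn3, -2.97 for Card14, -2.85 for Cyb561, -2.59 for Sbsn, -2.50 for Atp10d, -2.43 for Wfdc21 and -1.98 for the synuclein Sncg. Other genes share 42.4% of the stretches searched in the transcript end of Sbsn. Against regular_diff these stood at 1.05 and -2.44 for Prtn3, 1.02 and -1.95 for Card14, 0.53 and -2.32 for Cyb561, 1.33 and -1.26 for Sbsn, 1.11 and -1.39 for Atp10d, 1.19 and -1.24 for Wfdc21 and 1.44 and -0.55 for Sncg, WT_CM first. Dlk1, an inhibitor of fat cell formation, went the other way, with 2.57 between the media, -1.22 under WT_CM and 1.35 under KO_CM. The fall of Dlk1 under WT_CM had an adjusted p of 0.0308, of 0.196 without regular_diff replicate 4, 0.0949 without regular_diff replicate 6, 0.201 without WT_CM replicate 1 and 0.0505 without WT_CM replicate 2 (edgeR's quasi-likelihood test, Benjamini-Hochberg; range over the alternatives 0.0119 to 0.422). Without these libraries its log2 fold change lay between -1.38 and -0.89, and with all libraries kept it was not called by DESeq2 (adjusted p 0.0642) or after thinning (0.422), so its place among the 8 is uncertain.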

How the results depend on the processing

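Leaving out both doubted libraries (preadipocyte replicate 5 and KO_CM replicate 1), thinning all libraries to the smallest total, removing a trend over GC content and choosing the differentiation sets in a fit of only the preadipocyte and regular_diff libraries were chosen after the data were seen. Of 251 gene results examined, 199 kept their direction and their side of the threshold under every alternative that gave a value, and of 71 list results 54 did; the other 17 lists were lost with an estimated correlation. DESeq2 lost 17 of 241 gene results, thinning lost 19 of 232, and leaving out both doubted libraries lost 8, gained 6 and reversed 1 of 251. Leaving out 1 replicate at a time kept 1387 of 1506 gene results and 407 of 426 list results. The cause of these changes was not tested. The sign turned for 3 genes, none of them called: Cxcl1 in KO_CM against WT_CM was at -0.01 without both doubted libraries and between -0.02 and 0.47 with 1 replicate left out, Plin1 in WT_CM against regular_diff was at -0.06 after thinning and between -0.02 and 0.04 with 1 replicate left out, and Col1a1 in that comparison was at -0.06 after thinning. With a change of at least 2-fold required, the counts were 2480, 298, 1557 and 1054 in the order of the report, and the overlap 208, since fewer genes can pass. For WT_CM against regular_diff, 943 genes became 1480 with only the 6 libraries compared, 1445 without both doubted libraries (all 943 were tested and called there too, in the same direction), 506 after thinning, and 595 (without regular_diff replicate 4) to 711 with 1 replicate left out, among them 621 without regular_diff replicate 6. Leave-one-out counts were 4338 to 4905 for regular_diff against preadipocyte, 2834 to 3044 for KO_CM against regular_diff and 2174 to 2305 for KO_CM against WT_CM. With the sets of that fit of 6 libraries, the score difference was -44.6 and camera gave p-values of 5.56e-65 and 9.57e-51. The score difference lay between -43.5 and -44.9 over the other alternatives, at -46.2 after thinning, and between -46.0 and -44.4 with 1 replicate left out. Some calls were gained. In WT_CM against regular_diff, Cebpa reached an adjusted p of 0.00454 and Fabp4 one of 0.0198 with only the 6 libraries compared (ranges 0.00454 to 0.17 and 0.0198 to 0.959), and in KO_CM against WT_CM Trp53 reached 0.0126 without both doubted libraries (range 0.0126 to 0.622; edgeR's quasi-likelihood test, Benjamini-Hochberg). With the replicate number as a replicate block, 4752 genes were called for regular_diff against preadipocyte and 2519 for KO_CM against WT_CM, and the differentiation sets had p-values of 1.83e-60 and 3.95e-50. Same-numbered libraries correlated at -0.01, 0.12 and 0.065 and at -0.041, 0.036 and -0.054. Pairs with different numbers lay between -0.11 and 0.083 and between -0.042 and 0.077. With so few pairs, these values do not settle whether the numbers pair the samples. The block kept 127 of 131 gene and 38 of 39 list results. List medians changed sign with library size alone for complement, immunosuppressive and TGF-beta genes under differentiation, glucocorticoid genes under WT_CM, epithelial markers under KO_CM, and antigen presentation, unfolded protein and TGF-beta genes between the media. The depth of the KO_CM libraries limits calls of low genes there.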

Other observations

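The tests of where transcripts in preadipocyte replicate 5 came from and of the genes low in 2 libraries were chosen after those results were seen, and some of their criteria were revised after first results; the tests of the score after thinning, of a mixture and of other splits were set before their results were seen. As alternative settings for single genes and counts, thinning and leaving out both doubted libraries (preadipocyte replicate 5 and KO_CM replicate 1) were chosen after the data were seen.

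Matrix, progenitor and antigen presentation genes also moved under WT_CM against regular_diff. Of 17 fibrillar matrix genes 8 rose and 1 fell (9 and 1 adjusted over the list alone), the thrombospondin Thbs1 by 1.69 ± 0.16 and periostin (Postn) by -1.53 ± 0.30. Of 14 progenitor genes 5 rose and 2 fell (5 and 2 adjusted over the list alone), Ccn5 by 2.48 ± 0.42, Pdgfrb by -0.56 ± 0.16 and Dlk1 by -1.22 ± 0.37. Of 14 antigen presentation genes 5 rose (6 adjusted over the list alone), the immunoproteasome subunit Psmb8 by 1.26 ± 0.28. Camera called these 3 lists at an adjusted p of at most 0.00598, and with an estimated correlation at an adjusted p of at most 0.0332. The genes passed at an adjusted p of at most 0.0308 (edgeR's quasi-likelihood test, Benjamini-Hochberg). The adjusted p of Postn was 0.0512 without WT_CM replicate 2 and 0.057 without WT_CM replicate 3 (range over the alternatives 1.39e-16 to 0.057), and that of Psmb8 was 0.0657 after thinning, at a log2 fold change of 1.19 (range 3.86e-05 to 0.0657). That of Pdgfrb was 0.206 without regular_diff replicate 6, and 0.051, 0.0765 and 0.162 without WT_CM replicate 1, 2 or 3 (range 0.000912 to 0.206). That of Dlk1 was 0.196 and 0.0949 without regular_diff replicate 4 or 6, and 0.201 and 0.0505 without WT_CM replicate 1 or 2 (range 0.0119 to 0.422). Pdgfrb was chosen after its value was seen. Of 10 contractile genes 4 also rose under WT_CM (4 adjusted over the list alone). Camera called that list at an adjusted p of 0.000525, and of 0.0145 with an estimated correlation.

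Genes of sugar and sterol metabolism were on further lists. Of 19 glycolysis and hypoxia genes 15 rose and 1 fell under differentiation (15 and 1 adjusted over the list alone), Egln3, an oxygen-sensing hydroxylase, by 5.16 ± 0.21 and Hk1 by -0.93 ± 0.13, at an adjusted camera p of 4.92e-08 and of 0.014 with an estimated correlation. In KO_CM against regular_diff 8 fell and 2 rose (8 and 2 adjusted over the list alone), Egln3 by -2.20 ± 0.18, Hk1 by 0.56 ± 0.14 and P4ha1 by 1.07 ± 0.25, at an adjusted camera p of 0.000587 and of 0.0878 with an estimated correlation. In KO_CM against WT_CM 8 fell and 2 rose (8 and 2 adjusted over the list alone), Hk1 by 0.36 ± 0.14 and P4ha1 by 0.66 ± 0.23, at an adjusted camera p of 0.000275 and of 0.066 with an estimated correlation. The genes passed at an adjusted p of at most 0.0476 (edgeR's quasi-likelihood test, Benjamini-Hochberg). In KO_CM against WT_CM, the adjusted p of Hk1 was 0.0975 and 0.0675 without WT_CM replicate 1 or 3, and 0.152 and 0.073 without KO_CM replicate 1 or 3 (range 0.0206 to 0.16). That of P4ha1 was 0.0585 and 0.102 without WT_CM replicate 1 or 2, and 0.0575 and 0.142 without KO_CM replicate 1 or 2, and 0.0509 with a replicate block (range 0.0194 to 0.15). In KO_CM against regular_diff the adjusted p of P4ha1 was 0.0978 after thinning, at a log2 fold change of 0.68 (range 0.000528 to 0.0978; edgeR's quasi-likelihood test, Benjamini-Hochberg). Hk1 and P4ha1 were chosen after their values were seen. Of 17 cholesterol synthesis genes 10 fell in KO_CM against WT_CM (10 adjusted over the list alone), Insig1 by -1.15 ± 0.22, at an adjusted camera p of 0.000251 and of 0.0392 with an estimated correlation.

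Of 20 cell cycle genes 17 fell under differentiation (18 adjusted over the list alone), the helicase subunit Mcm5 by -1.78 ± 0.28, at an adjusted camera p of 6.47e-05, but an adjusted p of 0.058 with an estimated correlation. In KO_CM against WT_CM 7 fell (8 adjusted over the list alone), thymidine kinase (Tk1) by -1.49 ± 0.22 and Birc5 by -1.27 ± 0.28, at an adjusted camera p of 0.019, but an adjusted p of 0.21 with an estimated correlation. Of 22 interferon-stimulated genes 7 rose and 1 fell in that comparison (7 and 1 adjusted over the list alone), Oasl2 by 2.44 ± 0.44 and Ifi27l2a by -1.11 ± 0.20, at an adjusted camera p of 0.0157, but an adjusted p of 0.199 with an estimated correlation. The genes passed at an adjusted p of at most 0.00092 (edgeR's quasi-likelihood test, Benjamini-Hochberg). Ifi27l2a was chosen after its value was seen. Of 9 adipokines 5 fell and 2 rose in KO_CM against regular_diff (5 and 2 adjusted over the list alone), Adm by 2.53 ± 0.18 and Angptl4 by 0.30 ± 0.10, and camera did not call the list, at an adjusted p of 0.705. The adjusted p of Angptl4 was 0.019, and 0.0779 and 0.0525 without KO_CM replicate 1 or 3 (edgeR's quasi-likelihood test, Benjamini-Hochberg; range 0.00122 to 0.0779); Angptl4 was chosen after its value was seen. Of 17 p53 target genes 2 rose and 8 fell under differentiation (2 and 8 adjusted over the list alone), at an adjusted camera p of 0.0391, but an adjusted p of 0.0742 with an estimated correlation and of 0.0571 without regular_diff replicate 4 (range 0.0159 to 0.0742). In the other comparisons, in the order of the report, the p53 list stood at adjusted camera p-values of 0.535, 0.667 and 0.363.

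Cd274, which encodes the checkpoint ligand PD-L1, was removed by the filter on low counts, with 9 of 4834261 counts in preadipocyte, 25 of 4920925 in regular_diff, 27 of 5570964 in WT_CM and 2 of 2549799 in KO_CM libraries. In the fit with no filter it was called in regular_diff against preadipocyte, at a log2 fold change of 1.59 ± 0.58 and an adjusted p of 0.024, in KO_CM against regular_diff, at an adjusted p of 0.0163, and in KO_CM against WT_CM, at an adjusted p of 0.0239 (edgeR's quasi-likelihood test, Benjamini-Hochberg). The count ratios of the latter were 0.154 (95% counting interval 0.0177 to 0.619) and 0.162 (0.0187 to 0.644), so the direction rests on 2 counts in KO_CM. In WT_CM against regular_diff Cd274 was at -0.07 ± 0.47 and was not called. Gapdh counts ranged within groups, with 132, 3720 and 4868 in regular_diff replicates 4, 5 and 6. In KO_CM replicates 1, 2 and 3 they were 40, 2109 and 440. Other genes share 63.9% of the stretches searched in the transcript end of Gapdh. In KO_CM against regular_diff, transferrin (Trf) had a count ratio of 75.1 (95% counting interval 13.3 to 2990), lower in KO_CM, and Rps2 changed by -5.47 ± 1.61, with 82.2% and 83.5% of their transcript ends shared. The adjusted p of Rps2 was 0.0294, and 0.0568 and 0.0589 without regular_diff replicate 4 or 6, and 0.0909, 0.0944 and 0.0889 without KO_CM replicate 1, 2 or 3 (edgeR's quasi-likelihood test, Benjamini-Hochberg; range 3.34e-15 to 0.119).

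Of 18 epithelial, 15 leukocyte and 9 endothelial markers, 4, 2 and 1 were tested, too few for camera. In WT_CM against regular_diff, 1 epithelial marker rose (1 adjusted over the list alone), Krt19 by 1.76 ± 0.47 at an adjusted p of 0.0132, and 1 leukocyte marker (1 adjusted over the list alone), Cd14 by 1.38 ± 0.21 at an adjusted p of 3.85e-05 (edgeR's quasi-likelihood test, Benjamini-Hochberg). For Krt19 the adjusted p was 0.0785 and 0.0592 without regular_diff replicate 4 or 5 and 0.189 without WT_CM replicate 3 (range 0.00169 to 0.189). Under differentiation, 2 epithelial markers rose (2 adjusted over the list alone), Krt18 by 2.98 ± 0.44 and Krt8 by 1.44 ± 0.58, with the leukocyte marker Cd68 at 1.44 ± 0.42 and the endothelial marker Egfl7 at 0.87 ± 0.34, at an adjusted p of at most 0.0428 (edgeR's quasi-likelihood test, Benjamini-Hochberg). For Krt8 the adjusted p was 0.136 and 0.108 without preadipocyte replicate 4 or 5, and 0.0806, 0.0614 and 0.131 without regular_diff replicate 4, 5 or 6 (range 0.0329 to 0.136). For Egfl7 it was 0.164 without preadipocyte replicate 4 and 0.0719 and 0.0959 without regular_diff replicate 4 or 6 (range 0.0207 to 0.164). In KO_CM against regular_diff Krt7 changed by 1.84 ± 0.54, Krt18 by -1.53 ± 0.43, Cd68 by -1.43 ± 0.51 and Cd14 by 0.73 ± 0.26, at an adjusted p of at most 0.03 (edgeR's quasi-likelihood test, Benjamini-Hochberg). For Krt7 the adjusted p was 0.0731 without KO_CM replicate 1 (range 0.0017 to 0.0731), for Krt18 0.108, at -0.88, without KO_CM replicate 2 (range 0.00165 to 0.108), for Cd68 0.129 without regular_diff replicate 5 and 0.152 and 0.129 without KO_CM replicate 2 or 3 (range 0.0103 to 0.152), and for Cd14 0.0808 without regular_diff replicate 4 and 0.0992 without KO_CM replicate 3 (range 0.0164 to 0.162). In KO_CM against WT_CM Krt7 was at 1.66 ± 0.52, Krt18 at -1.52 ± 0.43 and Cd14 at -0.65 ± 0.22, at an adjusted p of at most 0.0273 (edgeR's quasi-likelihood test, Benjamini-Hochberg). For Krt7 the adjusted p was 0.0756 without WT_CM replicate 3 and 0.124 and 0.0693 without KO_CM replicate 1 or 3 (range 0.00329 to 0.124), and for Krt18 0.0547 without WT_CM replicate 2 and 0.132, at -0.86, without KO_CM replicate 2 (range 0.0024 to 0.132). For Cd14 it was 0.1, 0.0608 and 0.0593 without WT_CM replicate 1, 2 or 3 and 0.101 and 0.114 without KO_CM replicate 1 or 2 (range 0.022 to 0.198). Other genes share 12.8% of the stretches searched in the transcript end of Krt18 and 11.1% in that of Egfl7.

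Preadipocyte replicate 5 held transcripts of differentiated cells, with a median share of 2.34% of the WT_CM level over 87 genes against 0.587% and 0.859% in replicates 4 and 6. With the mean of replicates 4 and 6 subtracted from this library and from the source, and regular_diff cells as the source, the 7 genes at least 4-fold higher in WT_CM would show the same share as the other 80, but they showed 10.9% against 1.03% of the regular_diff level, which argues against that source. With WT_CM cultures as the source the shares of the WT_CM level, subtracted in the same way, were 1.3% and 1.21%, and with KO_CM cultures, for the 26 genes at least 4-fold higher in WT_CM than in KO_CM and the other 61, shares of the KO_CM level were 5.18% and 4.53%. RNA or reads from either culture may be the source, and these were not separated. The first version of this test rested on 1 gene and was replaced, and the rule for KO_CM, first read as undecided, was made the same as for WT_CM after its value was seen; no biological explanation was tested.

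In preadipocyte replicate 5 and KO_CM replicate 1, 104 of 6421 genes were low in both, and deviations from the group means correlated at 0.539. The highest other pair of libraries of these groups shared 5, which argues against counting noise. After a trend over the GC content of whole transcripts was removed, 91 of the 104 stayed low. That argues against GC content of the whole transcript. The GC content of the 3′ ends that MARS-seq counts was not tested. Of the 104, 102 could be searched for shared stretches in the last 500 bases of their transcripts, and 45 have none among those searched, which argues against reads shared there for these. For the 57 with such a stretch, shared reads cannot be told apart from other causes: they make up 55.9% of the 102, against 41.1% of genes of like level, and the first criterion, that most of them have one, was met but dropped after that background was seen. No biological explanation was tested.

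The KO_CM libraries lay between preadipocyte and WT_CM libraries in the differentiation score. Thinned to the smallest total, the difference between KO_CM and WT_CM was -46.2, which argues against depth. A plain mixture of undifferentiated cells and cells like those under WT_CM would leave few genes outside the range of these groups, but 257 were called above both or below both in KO_CM, 197 above, such as Angptl7 and Saa3, and 60 below, and 253 without both doubted libraries. That argues against a mixture of cells like those of the preadipocyte and WT_CM groups as the whole cause. The preadipocyte group had no conditioned medium, so a mixture holding undifferentiated cells exposed to it was not tested. The p53 status of the cancer cells stays among the open explanations, as untested.

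Other splits of the 6 libraries into 3 and 3 are too few, at 10, for a share under 0.1, so they are given as values. Every other split mixes the groups, so their difference enters the spread within each side and part of it stays between the sides. The values of other splits are therefore not those of unchanged groups. The real split, 1 of 10, gave 4874, 943, 3290 and 2625 genes in the order of the report, against 0 as the highest of the other splits in each (edgeR's quasi-likelihood test, Benjamini-Hochberg). It called 19, 15, 17 and 20 lists, against 18, 8, 13 and 13. In KO_CM against WT_CM the medians of the raised and lowered sets were 0.806 and 0.888 in size, against 0.292 and 0.307.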
